A study of Mus musculus with 24 samples.

How the data were processed

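Gene expression was measured by RNA-seq in 12 libraries of mouse L4/5 DRG, m6A enrichment by MeRIP-seq in 10 libraries (6 IP and 4 input, all wild type), and single m6A sites by miCLIP in 2 wild-type libraries. Per the labels the mice were C57BL/6, the treatment was a sham operation or a sciatic nerve crush, RNA was extracted with Trizol and selected for poly(A), and libraries followed the Smart-seq2 protocol. The RNA-seq and MeRIP-seq tables deposited by the authors hold counts, unnormalised, per gene symbol. They were checked to be whole numbers. Levels in CPM are counts scaled by the TMM-adjusted library total. The authors' miCLIP lists give for each site a value of unit other, deposited as a score: it equalled, at every site to within 0.00001, the number of mutated reads divided by the number of reads over the base, so it is a mutated share. The submitters' processing notes list Trimmomatic, STAR, DESeq2 and the mm10 build without versions. The role of each, the counter, and the site caller are not given in the sources used here.

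Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups (13291 of 24421 symbols in RNA-seq, 14705 of 24411 in MeRIP-seq), and libraries were scaled by TMM. A quasi-likelihood model (glmQLFit, glmQLFTest) was fitted to all 12 RNA-seq libraries as 4 groups of 3, and another to all 10 MeRIP-seq libraries as 4 groups. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, and a gene was called at an adjusted p under 0.05. The RNA-seq comparisons were SNLD1 over naive in each genotype, Mettl14cKO over wild type in each condition, and the difference between the 2 injury effects. The MeRIP-seq comparisons were IP over input in each condition, its change with injury, and SNLD1 over naive within IP and within input libraries. IP and input totals are not comparable in absolute terms, so enrichment is relative. IP libraries were not treated as paired with inputs of the same number. The labels do not say that replicates are separate animals, so p-values measure only the spread between these samples.

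Gene lists, comparisons, named-gene rule and alternatives were fixed before the data were examined. The 20 lists covered regeneration-associated, immediate-early, ATF4 target, sensory channel and receptor, pan-neuronal, m6A machinery, ribosomal protein, translation factor, cholesterol synthesis, interferon-stimulated and cell cycle genes, and markers of satellite glia, Schwann cells, macrophages, neutrophils, fibroblasts, endothelial and mural cells, skeletal muscle, oligodendrocytes and erythrocytes. Sets were tested with limma 3.58.1 on voom values by camera with a preset correlation of 0.01, beside camera with an estimated correlation and fry, and adjusted over the lists of a comparison. The oligodendrocyte and erythrocyte lists had 2 tested members each and were not tested as sets. Satellite glia, fibroblast, skeletal muscle, m6A machinery, translation factor and cell cycle lists passed in no comparison. Genes were named when they were called, had a mean of at least 5 CPM and showed no overlap between the groups compared, up to the 10 largest changes per direction. Also named were up to 4 members of smallest p in each list, the m6A machinery, and Mettl14, Atf3, Sox11, Jun, Gap43 and Sprr1a. Where no gene passed, the 5 of smallest p per direction were named. Other genes (those called in both genotype comparisons, and list members beyond the 4) were chosen after their values were seen. The test of the mean of the regeneration-associated list permuted genotype within condition over all 400 assignments.

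Sites were read as 1-based positions of mm10 and assigned to gene spans of the GRCm38.p6 gene table, since exon annotation was not used here. The strand of a site was not compared with that of the gene, so an antisense site counts as the gene's own. The fixed plan had asked for exons. In all, 98.8% of sites in each list fell in a span, against 47.6% and 47.4% after a shift of 5 Mb. Of the count tables' symbols 23204 matched that table by symbol and 1096 by synonym, and 121 did not match. Sites were called shared at the same base and strand. Tagged genes had at least 1 site in either list. Shares carry 95% exact binomial intervals (Clopper-Pearson). These analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

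RNA-seq totals spanned 5707837 to 12639160 counts, a ratio of 2.21, and the median SE of a log2 fold change was between 0.238 and 0.243 for the 4 group comparisons and 0.340 for the difference between injury effects. MeRIP-seq totals spanned a ratio of 23.2, with naive IP library 2 (846785), SNLD1 input library 1 (927807) and SNLD1 IP library 2 (1534778) the smallest, and median SE values lay between 0.955 and 1.51. Replicates correlated across genes at 0.964 to 0.983 (Spearman) in RNA-seq and 0.626 to 0.863 in MeRIP-seq. The pipeline was tested on simulated data with 200 genes changed per comparison. It found 54% to 63% of 2-fold and 96% to 99% of 4-fold changes in the RNA-seq group comparisons, and called between 4 and 14 unchanged genes per comparison. The changed genes were drawn from those above a minimum mean count, and libraries were simulated independently. The shares thus do not cover the lowest tested genes or a structure shared between libraries.

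Alternatives were DESeq2 1.42.0, DESeq2 size factors, library totals alone (MeRIP-seq), no filter, a stricter filter (5 CPM in 3 libraries), the 6 libraries compared alone, a log2 threshold of 1, a block by replicate number, and each library left out in turn. Chosen after seeing the data were a covariate for the share of Y-linked counts, leaving out both IP replicate 3 libraries, a block by number within IP and within input libraries, the site subsets by reads, and each library left out in turn for the lists called. The block within IP and input was dropped for IP over input, which it would compare in replicate 1 only. Sexes were mixed within groups: by Ddx3y and Xist, wild-type naive library 3, wild-type SNLD1 library 1, Mettl14cKO naive libraries 1 and 3 and Mettl14cKO SNLD1 library 3 were female, and Mettl14cKO SNLD1 library 1 carried both (74.8 and 8.53 CPM). No deposited column was left out. Distances to stop codons and positions within exons were not analysed here.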

Results

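The data came from lumbar (L4/5) dorsal root ganglia (DRG) of mice, the clusters of sensory neuron cell bodies whose axons run in the sciatic nerve. For RNA-seq and MeRIP-seq, ganglia were taken from naive mice or 1 day after a sciatic nerve lesion (SNLD1). The control libraries are titled naive, while the treatment label of every library names a sham operation or a nerve crush, so whether the controls were sham-operated was not settled here. The RNA-seq table held 12 libraries, 3 for each combination of wild type or Mettl14 conditional knockout (Mettl14cKO) with naive or SNLD1. Its libraries held between 5707837 and 12639160 counts. The MeRIP-seq table, in which RNA pulled down with an antibody against N6-methyladenosine (m6A) is counted beside input RNA, held 10 wild-type libraries. These were 3 pulldown (IP) libraries and 2 inputs per condition, with between 846785 and 19653733 counts. Single-base m6A site lists came from miCLIP, with 1 library per condition, titled naive and SNL. The title of the SNL library does not give the day after the lesion. Levels are given in CPM, counts scaled by the TMM-adjusted library total, as mean ± SD with n = 3 unless another n is stated.

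Mettl14 encodes the partner of Mettl3 in the complex that writes m6A on messenger RNA, and its own transcript was read first as a check of the genotype labels. It stood at 23.4 ± 0.605 CPM in naive and 20.1 ± 0.650 CPM in SNLD1 wild-type ganglia, against 16.02 ± 2.49 and 15.6 ± 1.35 CPM in Mettl14cKO (n = 3 each). Every Mettl14cKO library (14.2 to 18.9 CPM) lay below every wild-type library (19.4 to 24.1 CPM). The log2 difference was −0.55 (SE 0.17) in naive DRG, with adjusted p = 0.316, and −0.36 (SE 0.17) at SNLD1, with adjusted p = 0.345, so neither passed the test over all genes. Mettl3 was also lower, by a log2 difference of −0.50 (SE 0.18, adjusted p = 0.459) and −0.60 (SE 0.18, adjusted p = 0.114). None of the 21 tested genes of the m6A machinery passed in any RNA-seq comparison. The counts cover whole genes and whole ganglia, so they do not tell a deleted exon from an intact one or one cell type from another.

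**Figure D1:**
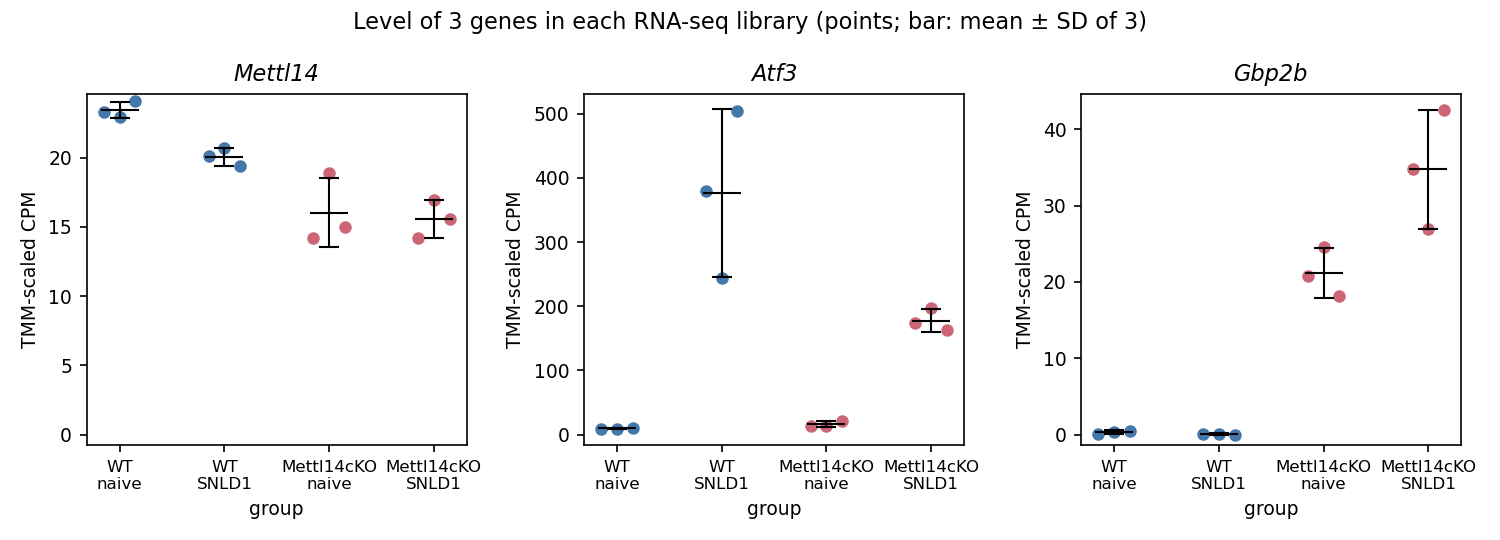
Level of Mettl14, Atf3 and Gbp2b in CPM in each of the 12 RNA-seq libraries (points), with the mean and SD of the 3 libraries of each group. Mettl14 was lower in every Mettl14cKO library, Atf3 rose with injury in both genotypes, and Gbp2b was nearly absent from wild type.

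The injury comparison in wild type asked which transcripts change in the ganglion 1 day after its peripheral axons are lesioned. Atf3, a transcription factor that marks axotomised sensory neurons, rose 38.6-fold, from 9.67 ± 1.31 to 376 ± 131 CPM (log2 5.27, SE 0.27, adjusted p = 2.49e-09). Flrt3 rose 9.66-fold to 895 ± 176 CPM (log2 3.27, SE 0.19), Sox11 rose 6.78-fold to 185 ± 47.4 CPM (log2 2.76, SE 0.26), and Gpr151 rose 11.1-fold to 54.4 ± 15.0 CPM. The cytokine Il6 went from 0.936 ± 0.504 to 12.3 ± 3.29 CPM. Gadd45a (log2 3.12, SE 0.31), Procr (3.003), Zfp729b (3.002), Steap1 (2.94) and Timp1 (2.76) completed the 10 largest rises. Here and in the later comparisons, largest means among called genes with a mean of at least 5 CPM over both groups and no overlap between them. The falls were smaller: Pcdh18 (log2 −1.33), Fam13a (−1.11), Nim1k (−1.06), Smad9 (−0.998), 1190002N15Rik (−0.99), Shox2 (−0.99), Fgf9 (−0.79) and Lrrn1 (−0.57). Gap43, a growth-cone protein already abundant in naive ganglia, did not pass (log2 0.23, SE 0.15, adjusted p = 0.861), and Sprr1a was too low to test.

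Among regeneration-associated genes, those known from axons that regrow, 18 of 30 rose and none fell in wild type, or 24 adjusted over the list alone. They included Bdnf (log2 1.68), Klf6 (1.17), Socs3 (2.38), Ankrd1 (3.53), Tnfrsf12a (1.996) and Plaur (2.72), and the list median was 1.21 (set test adjusted p = 3.09e-52, and adjusted p = 0.00457 with an estimated correlation). Of 18 immediate-early genes, Atf3, Fosl2 (log2 1.39) and Jun (1.305) rose, or 6 adjusted over the list alone (adjusted p = 6.89e-07, and adjusted p = 0.0577 with an estimated correlation). Interferon-stimulated genes had a median of 0.93, with Ifit1 (log2 2.45), Stat2 (1.01) and Mx2 (1.53) among the 17 tested rising, or 10 adjusted over the list alone (adjusted p = 1.02e-14, and adjusted p = 0.0577 with an estimated correlation). Cholesterol synthesis genes were higher in 20 of 23 cases with a median of 0.25, and Hsd17b7 (0.98) passed, or 4 adjusted over the list alone (adjusted p = 9.15e-08, and adjusted p = 0.0173 with an estimated correlation). Integrated stress response (ATF4) targets (median 0.17) and macrophage markers (median 0.36) were higher, and myelinating Schwann cell markers lower (median −0.19), as sets. Single libraries carried much of this: without SNLD1 library 3 ATF4 targets stood at 0.11 (camera, adjusted p = 0.0671). Macrophage markers stood at −0.10 without SNLD1 library 2 (camera, adjusted p = 0.353) and 0.63 without naive library 2, and missed without naive library 1 (camera, adjusted p = 0.188). Schwann cell markers stood at −0.04 without SNLD1 library 1 (camera, adjusted p = 0.707), −0.13 without naive library 3, −0.30 without naive library 2, and −0.31 without SNLD1 library 2 or 3. Of these 3 lists, 1, 0 and 0 members passed adjusted over the list alone, and the set calls ended with adjusted p = 0.103, 0.456 and 0.505 with an estimated correlation. Gfap, a marker of reactive satellite glia, went from 0.307 ± 0.135 to 4.11 ± 1.64 CPM, and the translation factor Eif3b rose by a log2 of 0.83, while neither list passed as a set.

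In all, 126 genes were higher and 10 lower after injury in wild type (edgeR, 13291 genes tested). Without wild-type naive library 1, naive library 3 or SNLD1 library 3 the higher count fell to 60, 63 and 74, and the lower count to 1 in each. The lower count was 2 without SNLD1 library 1 and 5 without SNLD1 library 2. Of 26 named genes that passed, Atf3, Il6, Gpr151, Flrt3, Gadd45a, Procr, Zfp729b, Steap1, Timp1, Sox11, Gfap, Ifit1 and Stat2 passed without any 1 library. The others did not: the adjusted p without 1 library reached 0.1495 for Jun, 0.178 for Fosl2, 0.224 for Mx2, 0.0753 for Eif3b, 0.0795 for Hsd17b7, and between 0.109 (Pcdh18) and 0.256 (Smad9) for the 8 genes that fell. With only the 6 libraries compared in the fit, Jun (adjusted p = 0.0683), Mx2 (0.0799) and all of the named falls except Fam13a (0.05001 to 0.139) no longer passed, and Lrrn1 also missed with size factors (0.0507), without a filter (0.0930) and with the Y-linked share as a covariate (0.0550).

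The same comparison in Mettl14cKO asked whether the response runs when Mettl14 is reduced. Atf3 rose 10.8-fold, from 16.3 ± 4.30 to 178 ± 17.6 CPM (log2 3.44, SE 0.25, adjusted p = 4.53e-07), and Flrt3 rose 4.04-fold to 594 ± 57.3 CPM (log2 2.01, SE 0.18). Sox11 rose 4.86-fold to 107 ± 6.21 CPM (log2 2.28), Bdnf 3.74-fold to 285 ± 41.0 CPM (log2 1.90) and Jun 4.03-fold to 15.97 ± 3.06 CPM (log2 2.01). Il6 went from 0.232 ± 0.225 to 11.8 ± 3.88 CPM (log2 5.51, or 6.21 without Mettl14cKO naive library 1). The other large rises were Saa1 (log2 3.49, or 4.10 without naive library 2), Iigp1 (3.02), Gadd45a (2.85), Steap1 (2.48), Tifa (2.46), Zfp729b (2.31), the serotonin synthesis enzyme Tph1 (2.50) and the mast cell protease Tpsab1 (2.34), with Tph1 and Tpsab1 moving to 3.55 and 3.15 without naive library 3. Falls were seen for the transcription factor Ebf3 (log2 −1.12), the itch receptor Mrgpra3 (−1.07), Cdh11 (−0.86), Map7 (−0.86), Lonp1 (−0.74), Sos1 (−0.73) and Hecw1 (−0.67). Gap43 again did not pass (log2 0.06).

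In Mettl14cKO 13 of 30 regeneration-associated genes rose, or 17 higher and 1 lower adjusted over the list alone, with 26 of 30 above 0 and a median of 0.82 (adjusted p = 3.06e-23, and adjusted p = 0.0293 with an estimated correlation). All 18 immediate-early genes were above 0 (median 0.61, adjusted p = 1.19e-09, and adjusted p = 0.0293 with an estimated correlation). Of these Atf3, Jun and Btg2 (log2 0.92) rose, or 8 adjusted over the list alone. Cholesterol synthesis genes had a median of 0.38, with Stard4 (log2 1.10) among those rising, or 7 adjusted over the list alone (adjusted p = 3.36e-11, and adjusted p = 0.00996 with an estimated correlation). Interferon-stimulated genes had a median of 0.71, with Ifit1 (1.89) and Rsad2 (1.03) rising, or 8 adjusted over the list alone (adjusted p = 7.94e-10, and adjusted p = 0.124 with an estimated correlation). All 83 cytoplasmic ribosomal protein genes were above 0 (median 0.41, or 0.16 without SNLD1 library 2 and 0.66 without SNLD1 library 3) although no member passed, and that set call ended with adjusted p = 0.466 with an estimated correlation. Sensory neuron channels and receptors were lower as a set (median −0.13, or −0.23 without naive library 2), with Mrgpra3 passing among 34. That call ended without naive library 3 (−0.05; camera, adjusted p = 0.201) and SNLD1 library 2 (−0.08; camera, adjusted p = 0.231), and it ended with adjusted p = 0.457 with an estimated correlation.

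In all, 83 genes were higher and 8 lower after injury in Mettl14cKO. A split of the same libraries that mixed naive and SNLD1 called more genes, 161. The higher count was 55, 52 and 48 without naive library 1, naive library 3 and SNLD1 library 1. The lower count was 2, 5 and 2 without naive libraries 1, 2 and 3, 0 without SNLD1 library 1 or 2, and 16 without SNLD1 library 3. Of 26 named genes that passed, 15 passed without any 1 library, among them Il6, Saa1, Atf3, Iigp1, Gadd45a, Steap1, Tifa, Zfp729b, Flrt3, Bdnf, Jun, Stard4, Ifit1 and Sox11. The adjusted p without 1 library reached 0.0619 for Tph1, 0.180 for Tpsab1, 0.0806 for Mrgpra3, 0.142 for Btg2, 0.185 for Rsad2, and between 0.136 (Ebf3) and 0.260 (Map7) for the other genes that fell. With only the 6 libraries compared in the fit, Btg2 (adjusted p = 0.0736), Tpsab1 (0.0871), Ebf3 (0.0642), Map7 (0.0862), Lonp1 (0.0736), Sos1 (0.0990) and Hecw1 (0.0924) no longer passed. Tpsab1 also missed with DESeq2 (0.251) and with the Y-linked share as a covariate (0.0805), a setting that ended the calls of Rsad2 (0.0613), Lonp1 (0.0544), Sos1 (0.0580) and Hecw1 (0.0580) too, and Lonp1 missed without a filter (0.0552).

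The 2 genotypes shared 56 genes called higher after injury, where 0.787 would be shared by chance (Fisher's exact test p = 1.19e-98), and none called lower. Of the 126 genes higher in wild type, 124 were also above 0 in Mettl14cKO, and 106 had a smaller change there (medians 1.48 and 0.998). Choosing genes by their wild-type change favours this outcome, and of the 83 genes chosen by their Mettl14cKO change, 47 changed more in Mettl14cKO. The test of the difference between the 2 injury effects called no gene (0 of 13291 with edgeR, 492 at an unadjusted p under 0.05, 665 by chance, and 3 lower with DESeq2). The smallest p-values on the lower side belonged to Msh6 (log2 −1.45, SE 0.26, adjusted p = 0.228), Atf3 (−1.84, SE 0.33, adjusted p = 0.228), Flrt3 (−1.26, SE 0.25, adjusted p = 0.361), Sertm1 (−2.14) and Star (−1.81). On the higher side stood Mc4r (1.83), Ntf3 (1.91), Rbp4 (1.95), Angptl7 (1.34) and Mta2 (1.26), each with adjusted p = 0.998. The difference was −0.48 for Sox11, 0.71 for Jun, −0.17 for Gap43 and 0.19 for Mettl14. Across regeneration-associated genes the mean rise was 1.60 in wild type and 1.21 in Mettl14cKO, a difference of −0.39 (exact permutation of genotype within condition, 400 assignments, two-sided p = 0.205, adjusted p = 0.875). The permutation assumes no genotype effect in either condition. A genotype effect widens its spread, so its p is not a test of equal rises alone. In simulated single genes above a minimum mean count, 84% of 4-fold and 20% of 2-fold differences between injury effects were found. Most differences of 2-fold would thus be missed.

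**Figure D2:**
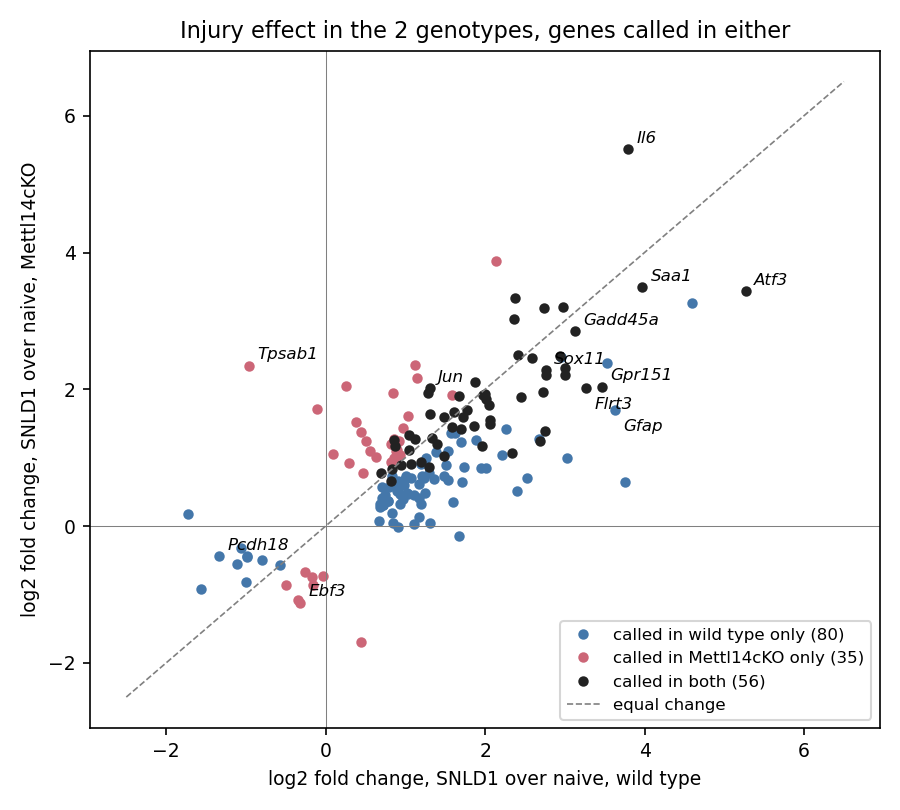
Log2 fold change with injury in wild type (horizontal axis) against Mettl14cKO (vertical axis) for genes called in either genotype. Most points lie in the upper right quadrant, 56 genes were called higher in both, and Atf3 and Flrt3 lie below the diagonal.

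The genotype comparison in naive ganglia asked what differs without a lesion. The largest differences were transcripts nearly absent from wild type: Gbp2b stood at 21.2 ± 3.26 CPM in Mettl14cKO against 0.346 ± 0.224, Fn3krp at 20.3 ± 3.53 against 0.301 ± 0.219, and AI429214 at 10.1 ± 7.31 against 0.154 ± 0.0674. Their fitted log2 values of 5.83, 5.91 and 5.81 moved to 6.42 and 6.75 without wild-type naive library 3 and to 5.04 without Mettl14cKO naive library 2. Pam, an enzyme that amidates neuropeptides, was 3.66-fold higher at 47.9 ± 4.26 CPM (log2 1.87, SE 0.17, adjusted p = 1.21e-05). Edem1 (log2 1.51), the growth factor gene Nrg1 (1.49) and the channel gene Kcnj13 (1.38) were also higher, as were Elmo1 (1.72), Olfr920 (1.36) and A930005H10Rik (1.27). Lower transcripts included Ccdc109b, a mitochondrial calcium channel subunit (13.8 ± 1.54 against 44.3 ± 7.19 CPM, log2 −1.67), Fcrls (−1.69), Rbp7 (−1.67), Them5 (−1.64), Efcab7 (−1.34), Cyb5d2 (−1.32), Phtf1 (−1.299), Ibsp (−1.21) and Sh3bgr (−1.16). 2610507I01Rik was lower too (log2 −2.33, or −3.85 without Mettl14cKO naive library 2). The heavy neurofilament gene Nefh, which marks large myelinated sensory neurons, was lower at 413 ± 9.15 against 693 ± 98.2 CPM (log2 −0.75, SE 0.14, adjusted p = 0.0305).

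No cholesterol synthesis gene was above 0 in naive Mettl14cKO (0 of 23, median −0.20, set adjusted p = 2.77e-07, and adjusted p = 0.0277 with an estimated correlation), with 3 lower adjusted over the list alone. ATF4 targets were higher in 19 of 23 cases (median 0.24, adjusted p = 1.06e-05, and adjusted p = 0.0277 with an estimated correlation), with 4 higher adjusted over the list alone. In neither list did a member pass over all genes. Pan-neuronal genes were lower (median −0.17, Nefh passing among 18, or 3 adjusted over the list alone), and so were myelinating Schwann cell (−0.16) and neutrophil markers (−1.38), while interferon-stimulated genes were higher (0.31). These 4 set calls ended with adjusted p = 0.304, 0.935, 0.935 and 0.935 with an estimated correlation, and the last 3 rested on single libraries. Neutrophil markers stood at −0.12 without wild-type naive library 2 (camera, adjusted p = 0.928) and missed without Mettl14cKO naive library 1 or 3 (camera, adjusted p = 0.0573 and 0.0762). Schwann cell markers stood at −0.32 without Mettl14cKO naive library 1 and missed without any other (camera, adjusted p = 0.0517 to 0.321), with −0.08 without Mettl14cKO naive library 2. Interferon-stimulated genes stood at 0.13, 0.18 and 0.05 without wild-type naive library 1 and Mettl14cKO naive libraries 2 and 3, each missing (camera, adjusted p = 0.722, 0.0574 and 0.411), and at 0.56 and 0.504 without wild-type naive library 2 and Mettl14cKO naive library 1. Pan-neuronal genes stood at −0.08 without Mettl14cKO naive library 1.

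In all, 23 genes were higher and 15 lower in naive Mettl14cKO. Those counts were 9 and 3, 14 and 3, and 15 and 4 without wild-type naive libraries 1, 2 and 3, and 12 and 2 and 17 and 2 without Mettl14cKO naive libraries 2 and 3. Of 21 named genes that passed, Fn3krp, Gbp2b, AI429214, Pam, Edem1, Nrg1 and Kcnj13 passed without any 1 library. The adjusted p without 1 library reached 0.165 for Nefh, 0.0542 for Ccdc109b, 0.105 for Fcrls, 0.0915 for A930005H10Rik, 0.138 for Elmo1, 0.144 for Rbp7, 0.131 for Them5, and between 0.162 (Cyb5d2) and 0.305 (Olfr920) for the other 7. Nefh also missed with only the 6 libraries compared in the fit (adjusted p = 0.0832). 2610507I01Rik missed with DESeq2 (0.116), size factors (0.0508) and the stricter filter (0.0689), Olfr920 with size factors (0.0560) and the stricter filter (0.0635), Phtf1 with the stricter filter (0.0521), and Sh3bgr with that filter (0.0521) and the replicate block (0.0501).

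The genotype comparison at SNLD1 asked how Mettl14cKO and wild-type ganglia differ after the lesion. Atf3 was lower in Mettl14cKO, at 178 ± 17.6 against 376 ± 131 CPM (log2 −1.08, SE 0.22, adjusted p = 0.0202), and so were the injury-induced factor Klf6 (−0.80, adjusted p = 0.0321) and the calcium channel subunit Cacna2d1 (−0.73, adjusted p = 0.0332). Sensory transcripts were also lower: Mrgpra3 (log2 −1.03, SE 0.20), the nociceptor sodium channel Scn10a (−0.64, SE 0.16) and Nefh (310 ± 14.05 against 586 ± 49.4 CPM, −0.92, SE 0.14, adjusted p = 0.00360). The neurotrophin Ntf3 was 13.95 ± 0.550 CPM in Mettl14cKO against 1.41 ± 0.729 (log2 3.32). Transcripts nearly absent from wild type were Gbp2b (34.7 ± 7.79 against 0.0892 ± 0.0797 CPM), Fn3krp (19.2 ± 4.65 against 0.938 ± 0.462 CPM), Tpsab1 (10.5 ± 2.30 against 0.0381 ± 0.0660 CPM) and AA465934 (15.8 ± 15.5 against 0.0381 ± 0.0660 CPM). Rbp4 (log2 3.03), Dpep1 (2.69), the macrophage receptor Cd163 (2.32), Fgfbp1 (2.27) and Mpzl2 (2.01) were higher too. Single markers of other cell types were higher: Ncmap of Schwann cells (log2 1.18), Pdgfra (1.43) and Dcn (0.97) of fibroblasts, and Tagln (1.60) and Ly6c1 (1.11) of vessels. The Schwann cell and fibroblast lists did not pass as sets, and their mean log2 levels were 4.88 and 4.61 in wild type and 4.896 and 4.58 in Mettl14cKO. The largest falls were Fcrls (log2 −1.92), Igfbp3 (−1.90), Mstn (−1.72), Dok5 (−1.50), Itpr1 (−1.48), Star (−1.45), Lect1 (−1.41), Car1 (−1.40), Rbp7 (−1.37) and Msh6 (−1.35). Sox11 (log2 −0.80, adjusted p = 0.112), Gap43 (−0.34, adjusted p = 0.286) and Jun (−0.06) did not pass.

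At SNLD1 only 3 of 30 regeneration-associated genes were above 0 in Mettl14cKO (median −0.26), with Atf3, Klf6 and Cacna2d1 lower over all genes, or 9 adjusted over the list alone (set adjusted p = 3.29e-07, and adjusted p = 0.353 with an estimated correlation). That median was −0.425 and −0.17 without wild-type SNLD1 libraries 2 and 3, and −0.46 and −0.13 without Mettl14cKO SNLD1 libraries 2 and 3. Ribosomal protein genes were above 0 in 82 of 83 cases (median 0.48, or 0.20 without Mettl14cKO SNLD1 library 2) with none passing (set adjusted p = 1.49e-16, and adjusted p = 0.497 with an estimated correlation). ATF4 targets (median 0.18) and endothelial and mural cell markers (0.30) were higher as sets. Sensory neuron channels and receptors (−0.15), pan-neuronal genes (−0.12) and cholesterol synthesis genes (−0.16) were lower. Adjusted over the list alone, 3 endothelial and mural markers were higher, 1 sensory gene was higher and 3 lower, and 4 pan-neuronal genes were lower. All 7 set calls ended with an estimated correlation, at adjusted p = 0.353 or 0.497, and 5 ended without 1 library. ATF4 targets stood at 0.09 without wild-type SNLD1 library 2 (camera, adjusted p = 0.244) and 0.28 without library 3, and missed without wild-type SNLD1 library 1 (camera, adjusted p = 0.0681) or Mettl14cKO SNLD1 library 3 (0.165). Endothelial and mural markers stood at 0.14 without wild-type SNLD1 library 1 (camera, adjusted p = 0.177), 0.58 without library 2 and 0.52 without Mettl14cKO SNLD1 library 1, and missed without Mettl14cKO SNLD1 library 3 (0.126). Sensory genes stood at −0.25 without wild-type SNLD1 library 2 and −0.08 without Mettl14cKO SNLD1 library 2 (camera, adjusted p = 0.236), and missed without wild-type SNLD1 library 1 (0.176) or 3 (0.0883). Pan-neuronal genes stood at −0.25 and −0.07 without wild-type SNLD1 libraries 2 and 3 and −0.1998 without Mettl14cKO SNLD1 library 3, and missed without wild-type SNLD1 library 1 (camera, adjusted p = 0.0681). Cholesterol synthesis genes missed without Mettl14cKO SNLD1 library 3 (camera, adjusted p = 0.0908).

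In all, 126 genes were higher and 68 lower in Mettl14cKO at SNLD1. Those counts were 34 and 23, 93 and 41, and 39 and 17 without wild-type SNLD1 libraries 1, 2 and 3, and 28 and 9 and 65 and 19 without Mettl14cKO SNLD1 libraries 1 and 2. Atf3 no longer passed without wild-type SNLD1 library 1 (adjusted p = 0.0635), wild-type SNLD1 library 3 (0.140) or Mettl14cKO SNLD1 library 1 (0.111). Mrgpra3 no longer passed without wild-type SNLD1 library 1 (0.0569), Mettl14cKO SNLD1 library 1 (0.0868) or library 2 (0.0717). Of 31 named genes that passed, 15 passed without any 1 library: Gbp2b, Tpsab1, Fn3krp, Ntf3, Rbp4, Dpep1, Fgfbp1, Mpzl2, Fcrls, Itpr1, Lect1, Msh6, Nefh, Pdgfra and Tagln. The adjusted p without 1 library reached 0.215 for Klf6, 0.195 for Cacna2d1, 0.231 for Scn10a, 0.0610 for Cd163 and Ncmap, 0.193 for AA465934, and between 0.0868 (Star) and 0.1498 (Igfbp3) for Mstn, Dok5, Car1, Rbp7, Dcn and Ly6c1. With only the 6 libraries compared in the fit, Klf6 (adjusted p = 0.0682), Cacna2d1 (0.0542), Scn10a (0.0747), Ncmap (0.0538), Dok5 (0.0629) and Rbp7 (0.0593) no longer passed, and AA465934 missed with the stricter filter (0.0544) and the Y-linked covariate (0.0504). The fitted log2 value of Tpsab1 (7.49) moved to 9.35 without wild-type SNLD1 library 2, Rbp4 moved to 3.70 without wild-type SNLD1 library 3, and Dpep1 and Cd163 moved to 2.08 and 1.70 without Mettl14cKO SNLD1 library 2.

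The naive and SNLD1 genotype comparisons, which shared no library, called 20 of the same genes higher (0.218 by chance) and 11 lower (0.0767 by chance). Besides Gbp2b, Fn3krp, AI429214, Pam, Edem1, Nrg1, Kcnj13, Elmo1, Fcrls and Nefh these included Anxa4 (log2 0.94 naive, 0.84 SNLD1), Gng13 (3.11, 3.46), Shoc2 (1.18, 1.03), Tifa (−0.87, −1.002) and the heavily m6A-tagged Prune2 (−0.89, −0.95). Mettl14 lies on chromosome 3 (mm10, 1-based positions 123368295 to 123385990), and 10 of the 31 shared genes lie on that chromosome: Fcrls, Them5, Pi4kb, Phtf1, A930005H10Rik, Tifa, Ccdc109b, Gstcd, Gbp2b and Ifi44l. Gbp2b spans positions 142594816 to 142619179, and Ccdc109b spans 129914960 to 129970211. Random sets of as many tested genes had a median of 1 on chromosome 3 (permutation p = 1e-04, the smallest the 10000 draws can give).

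**Figure D3:**
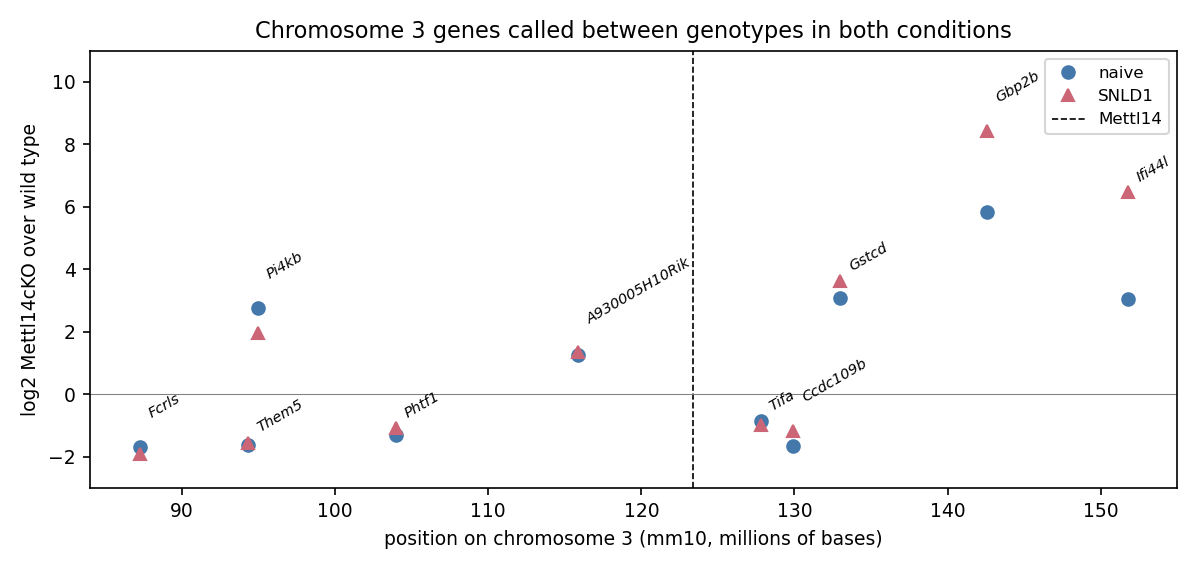
Log2 fold change in Mettl14cKO over wild type, naive and SNLD1, of the 10 chromosome 3 genes called in both conditions against their position in Mb (mm10). The dashed line marks Mettl14, and the genes lie on both sides of it. They were chosen for a change in the same direction in both conditions.

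**Figure D4:**
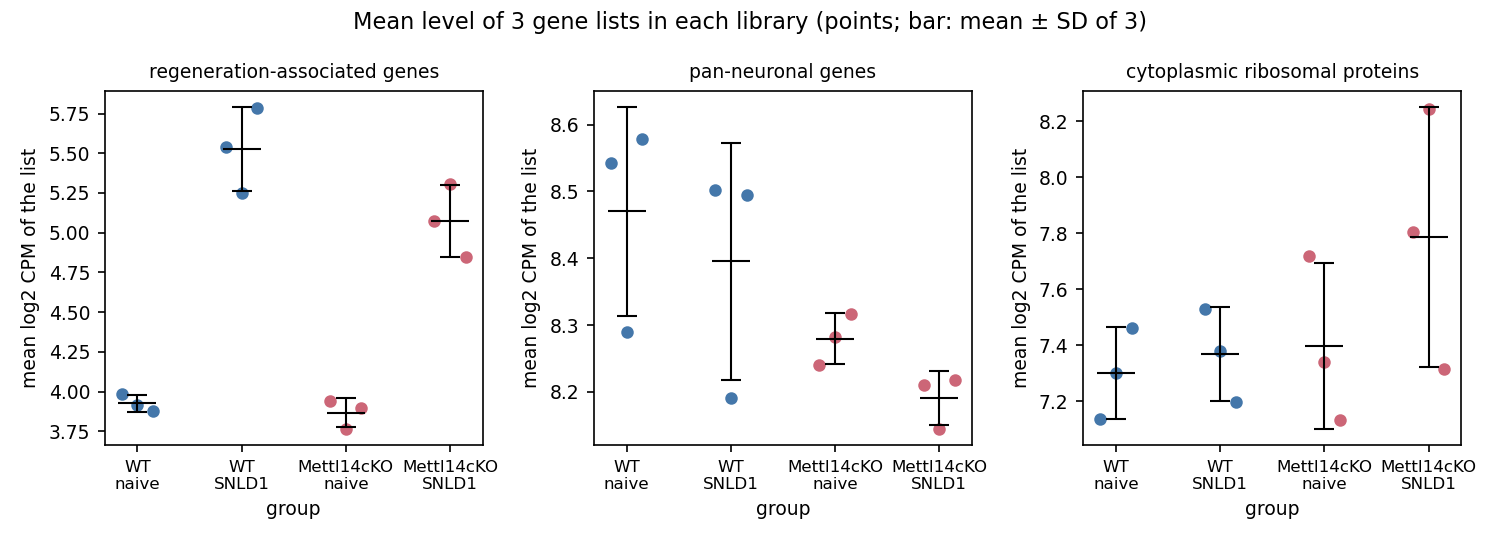
Mean log2 CPM of regeneration-associated, pan-neuronal and cytoplasmic ribosomal protein genes in each RNA-seq library by group. Regeneration-associated genes rose with injury in both genotypes, and ribosomal protein genes varied between the libraries within both Mettl14cKO groups.

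The MeRIP-seq comparisons asked which transcripts are enriched by the m6A antibody, and whether enrichment changes with injury. Atf3 was higher after injury in both kinds of library, at 2270 ± 1555 against 66.0 ± 76.4 CPM in the IP libraries (n = 3 each, log2 5.12, SE 1.06) and 536 ± 58.6 against 13.8 ± 5.44 CPM in the inputs (n = 2 each, log2 5.28, SE 1.304), with adjusted p = 1 in each. Its IP over input log2 ratio was 2.25 in naive DRG and 2.08 at SNLD1, a change of −0.16 (SE 1.40). Procr rose by a log2 of 4.47 in IP and 4.10 in input libraries. Of the 126 genes higher with injury in wild-type RNA-seq, 120 were above 0 in the inputs (median 1.33) and 124 in the IP libraries (median 1.29). Genes with miCLIP sites had a median IP over input of 0.31 in naive DRG against −0.12 for genes without (camera, adjusted p = 0.00397, and adjusted p = 0.233 with an estimated correlation). At SNLD1 the medians were 0.32 and −0.06 (camera, adjusted p = 0.0393, and adjusted p = 0.372 with an estimated correlation). With injury tagged genes were higher in the inputs (camera, adjusted p = 0.00197, and adjusted p = 0.291 with an estimated correlation) and the IP libraries (camera, adjusted p = 0.0444, and adjusted p = 0.395 with an estimated correlation). In wild-type RNA-seq they did not pass with injury (median difference −0.03, camera, adjusted p = 0.232). The SNL list alone tagged 1750 genes, so a rise with injury can itself bring a gene into the set. The change of enrichment did not pass for tagged genes (camera, adjusted p = 0.147), or passed downward against expression-matched genes (camera, adjusted p = 3.95e-06, and adjusted p = 0.0928 with an estimated correlation). The inputs differed from each other in the same measure: against the mean of its inputs, the matched excess of tagged genes was 0.51 in 1 naive and 1.18 in 1 SNLD1 input, beside 1.11, 0.851 and 0.388 in naive and 1.02, 0.849 and 0.348 in SNLD1 IP libraries.

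With edgeR no gene passed in any of the 5 MeRIP-seq comparisons (14705 genes tested). At an unadjusted p under 0.05 there were 915 for IP over input in naive DRG, 608 at SNLD1, 30 for the change with injury, 124 for injury in IP and 126 for injury in input libraries, where 735 would arise by chance. DESeq2 called 1, 0, 0, 8 and 1. The replicate block changes this for IP over input: with the replicate number as a common block 48 genes were higher and 1030 lower in naive DRG, and 44 and 892 at SNLD1. That block assumes that IP and input of the same number shift together. Their deviations across genes correlated at −0.355 and −0.387 in naive DRG and 0.00485 and −0.0613 at SNLD1. No input has the number 3, so the block cannot set IP replicate 3 against an input. Without both IP replicate 3 libraries, a choice made after seeing the data, 2 were higher and 257 lower in naive DRG, and 0 and 117 at SNLD1. The smallest p-values for IP over input in naive DRG belonged to Map3k11 (log2 4.97), H2afx (5.21) and Tbcc (3.95) on the higher and Ssr1 (−3.78) and Nmt2 (−3.88) on the lower side (adjusted p = 0.710), and at SNLD1 to Tor4a (5.47), Vamp5 (3.15), Gadd45g (3.51), Lars2 (−3.35) and Car1 (adjusted p = 0.791). Car1 had no count in the 3 SNLD1 IP libraries and 13.3 ± 13.1 CPM in the inputs (n = 2). IP libraries with the same number resembled each other across conditions (correlations of their deviations across genes 0.756, 0.570 and 0.821, against −0.502 to −0.219 for other numbers). With the number as a block within IP and within input libraries, chosen after seeing the data, 6 genes were higher with injury in the IP libraries: Atf3 (5.59), Gadd45a (3.06), Smim3 (2.66), Flrt3 (2.92), Procr (4.32) and Tifa (2.21). Atf3 (5.33) alone was higher in the inputs. With the common block, 1 gene passed for injury in the IP libraries. In simulations of the fit without a block 0% of 4-fold changes were found. Changes of 16-fold were found in 41% of cases for injury in IP libraries, 6% for naive IP over input and 0% for the other 3 comparisons. The simulations took their spread from that fit and drew libraries independently. The likeness of same-numbered IP libraries thus entered as noise, and the shares do not describe the fits with a block.

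The miCLIP lists asked where m6A lies at single bases. They held 14446 sites in naive and 18677 in SNL ganglia, all in the DRACH context of the m6A writer, and 83.5% and 82.7% had the GAC core. Whether the lists had been filtered for that context is not known, so the match says nothing about the quality of the sites. Most sites rested on 1 mutated read, 90.2% of naive and 89.7% of SNL sites, at a median coverage of 4 reads in each list. At the same base and strand 3832 sites were shared, 26.5% (95% exact binomial interval 25.8 to 27.3) of naive and 20.5% (19.9 to 21.1) of SNL sites, where intervals cover counting error only. Shared sites were covered more deeply, with median coverage of 6 and 8 reads against 3 and 4 for the others. Sites fell in 4358 genes in naive and 5053 in SNL, 3303 of them in both. The most sites lay in Map1a, Plec and Map1b: Map1a carried 105 and 102 sites (60 shared), Plec 92 and 97, and Map1b 63 and 67. With each gene span divided into 5 equal parts in the direction of the site's strand, the last part held 48.5% and 48.4% of assigned sites and the first 18.2% and 17.2%. Whole gene spans were used because exon annotation was not used here.

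Some regeneration-associated transcripts had more listed sites in SNL ganglia: Atf3 went from 0 to 15, Sox11 from 0 to 6, Bdnf from 0 to 7, Klf6 from 2 to 5, Socs3 from 1 to 5 and Cacna2d1 from 1 to 5. The whole SNL list held 1.29 times as many sites as the naive list. Jun had 19 and 25 sites (14 shared), and Gap43 had 2 and 4. Regeneration-associated genes with a site went from 9 to 19, and their sites from 44 to 112, while pan-neuronal genes went from 141 to 152 sites. The Atf3 site of highest mutated share lay at position 191183121 of chromosome 1 (mm10, 1-based, GGACC, mutated in 3 of 6 reads), and that of Sox11 lay at 27342411 of chromosome 12 (GGACC, 5 of 14 reads). Atf3, Sox11, Bdnf, Klf6 and Socs3 rose with injury in wild-type RNA-seq, so their sites were less detectable in naive ganglia. There Atf3 stood at 9.67 and Sox11 at 27.3 CPM, and the 6 Sox11 sites in SNL ganglia had 53 reads in all. Whether level accounts for the missing naive sites was not tested. Jun also rose with injury, and its 19 naive sites had 204 reads in all. With 1 library per condition the differences in sites were not tested. Mettl14, Mettl3, Flrt3, Il6 and Sprr1a had no listed site.

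The last comparison asked whether transcripts with m6A sites move together when Mettl14 is reduced or the nerve is lesioned. The 5611 tagged genes differed from 7680 untagged genes by a median log2 of −0.03 with injury in wild type (camera, adjusted p = 0.232) and −0.02 in Mettl14cKO (camera, adjusted p = 0.326). For genotype the difference was −0.03 in naive DRG (camera, adjusted p = 0.274) and −0.02 at SNLD1 (camera, adjusted p = 0.426), and for the difference between injury effects it was 0.00 (camera, adjusted p = 0.960). None of these passed. Genes with at least 10 sites had medians of −0.08 and −0.10 with injury in wild type and Mettl14cKO, −0.06 and −0.07 for genotype in naive DRG and at SNLD1, and 0.01 for the difference, against 0.00, 0.02, 0.01, 0.01 and 0.01 for genes without sites, which was not tested. Prune2 was among the transcripts lower in Mettl14cKO in both conditions. Of the 31 genes called in the same direction in both, 11 were tagged, against a median of 14 in matched random sets (permutation p = 0.883). That test was chosen after the results were seen.

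**Figure D5:**
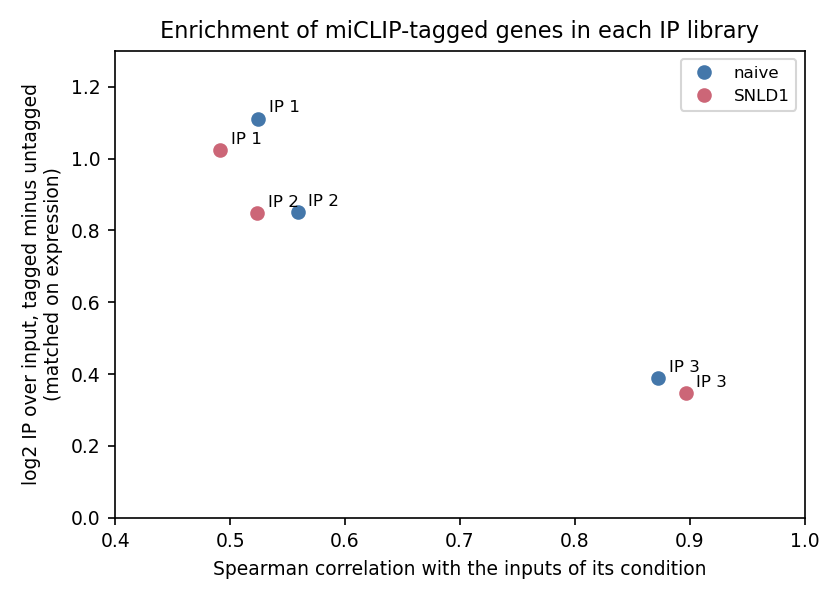
Excess of miCLIP-tagged over expression-matched untagged genes in log2 IP over input (vertical axis) against the Spearman correlation with the inputs of the same condition (horizontal axis) for each of the 6 IP libraries. IP library 3 of each condition lies apart, with an excess of 0.388 and 0.348 and a correlation of 0.873 and 0.897.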

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

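Of the tests in this part, the one of the share of neurons was chosen after the result was seen, as was leaving out each library in turn for the lists. Between the genotypes, the injury effect differed for regeneration-associated and for ribosomal protein genes in the set test with a preset correlation, and with injury the m6A enrichment differed for neutrophil markers and ribosomal protein genes.

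Regeneration-associated genes rose less in Mettl14cKO: 22 of the 30 had a difference below 0, with the smallest p-values in Atf3 (−1.84) and Flrt3 (−1.26) (list median −0.31, set test adjusted p = 1.448e-05, and adjusted p = 0.797 with an estimated correlation). The mean rise of 1.60 in wild type and 1.21 in Mettl14cKO differed by −0.39 (exact permutation p = 0.205). A lower share of neurons stays open: pan-neuronal genes differed by −0.01438 and their 95% interval began at −0.29. The regeneration-associated difference itself had an SE of 0.2116 and reached −0.2613 without 1 library, so the 2 lists were not told apart. The ribosomal protein share of the libraries stays open too. With it as a covariate 119.6% of the difference was left, with an SE of 0.2195. A decision by 1 library stays open: without wild-type SNLD1 library 3, 66.79% of the difference was left, and the list median was −0.10 (−0.61 and −0.58 without wild-type and Mettl14cKO SNLD1 library 2). A weaker injury response in Mettl14cKO may equally underlie it, which the exact test did not separate from regrouping.

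Ribosomal protein genes rose more with injury in Mettl14cKO (median 0.35, set test adjusted p = 6.687e-11, and adjusted p = 0.797 with an estimated correlation), with 80 of 83 above 0. Their mean log2 level in the 3 Mettl14cKO SNLD1 libraries was 7.80, 8.24 and 7.32, and the difference of 0.322 (exact permutation p = 0.420) was 0.0935 without Mettl14cKO SNLD1 library 2. The set call ended without that library too (median 0.09; camera, adjusted p = 0.181), and the median was 0.54 and 0.22 without Mettl14cKO naive libraries 1 and 3 and 0.59 without Mettl14cKO SNLD1 library 3.

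Of 60 splits that regrouped the libraries by genotype within condition, the real one included, 58 called at least as many lists as the real 2 (highest 13), so chance is not excluded for the list calls. The real split called 0 genes and gave a tagged-gene p of 0.960 (camera). All 60 splits are then as large in genes by construction, and 60 were as low in the tagged-gene p, which says nothing about chance. Other splits called up to 45 genes and reached a tagged-gene p of 3.226e-10, and the split with 45 keeps the genotypes apart at SNLD1 and mixes them in naive DRG, so it contains the genotype effect at SNLD1. Other splits of that kind called between 0 and 42, and the cause of the difference was not tested.

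The change of m6A enrichment with injury passed the set test for neutrophil markers (adjusted p = 0.04707) and ribosomal protein genes (adjusted p = 0.02571), in each case upward although the medians were −0.30 and −0.04. With an estimated correlation both stood at adjusted p = 0.987. Each call ended when any 1 of 5 of the 10 libraries was left out, and the medians ranged from −2.99 to 3.78 and from −1.699 to 2.67 with 1 library left out. No member of either list passed, and no biological explanation was tested.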

How the results depend on the processing

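The alternatives chosen after seeing the data were the Y-linked covariate, both IP replicate 3 libraries left out, the replicate block within IP and input, the site subsets by mutated and total reads, and each library left out in turn for the lists called. Except where stated the cause was not tested. Under the alternatives fixed beforehand 1802 values of single genes and lists stayed the same, 294 became weaker, 16 stronger and 54 reversed. In each count below, higher comes before lower. DESeq2 called 184 and 18 genes for injury in wild type, 146 and 42 in Mettl14cKO, 42 and 31 for genotype in naive DRG, 220 and 179 at SNLD1, and 0 and 3 for the difference between injury effects. Without a filter the counts were 232 and 24, 230 and 51, 107 and 84, 334 and 236, and 10 and 14. With a log2 threshold of 1, which only removes calls, the lower counts with injury were 5 and 3, and genotype at SNLD1 gave 83 and 35. With only the 6 libraries compared, so with fewer samples behind each variance, the lower counts with injury were 1 and 3, and 77 genes were higher by genotype at SNLD1. With the Y-linked covariate 24 genes were lower by genotype in naive DRG. With each library left out in turn the counts were 60 to 130 and 1 to 14 for injury in wild type, 48 to 100 and 0 to 16 in Mettl14cKO, 9 to 27 and 2 to 17 for genotype in naive DRG, 28 to 179 and 9 to 83 at SNLD1, and 0 and 0 to 1 for the difference. These fits leave 2 libraries in a group.

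In MeRIP-seq DESeq2 called 1 gene higher for IP over input in naive DRG, 8 for injury in IP and 1 in input libraries. No filter gave 3 and 6 in naive DRG, 4 and 2 at SNLD1, and 1 higher for injury in IP libraries. Without both IP replicate 3 libraries 2 and 257 genes passed for IP over input in naive DRG and 117 lower at SNLD1. In that setting Sprr1a over input at SNLD1 turned to 0.318. The Mettl14 injury effect in inputs turned to 0.0281 with DESeq2, 0.0308 with size factors and 0.0138 with library totals alone. With totals alone IP over input turned to 0.284 for Mettl14 in naive DRG and to 0.295 for Sox11 and 0.514 for Sprr1a at SNLD1. With an estimated correlation the lists called fell from 7, 6, 6, 7, 2 and 2 to 2, 3, 2, 0, 0 and 0 (injury in wild type and Mettl14cKO, genotype in naive DRG and at SNLD1, the difference, and the change of enrichment). Shared sites were 42.5% of naive and 34.2% of SNL sites within 50 nt, 10.1% and 8.21% among the sites of higher score, 21.9% and 16.3% with at least 2 mutated reads, and 50.2% and 34.7% with at least 10 reads. The score is the mutated share, and 90.2% of naive and 89.7% of SNL sites had 1 mutated read. A higher score therefore favours sites covered by few reads.

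The labels do not say that replicate numbers mark pairs. Same-numbered RNA-seq libraries of different groups had correlations of deviations between −0.112 and 0.693, not all above 0.1, so they were not treated as paired. Not every library correlated best with its own number: wild-type naive library 3 stood at 0.586 with wild-type SNLD1 library 1 and 0.0859 with library 3. With the replicate block 145 and 10 genes were called for injury in wild type, 117 and 16 in Mettl14cKO, 32 and 18 for genotype in naive DRG, 184 and 102 at SNLD1, and 0 and 0 for the difference. Same-numbered IP and input libraries of a condition had correlations of deviations between −0.387 and 0.00485. For IP over input the replicate block gave 48 and 1030 genes in naive DRG and 44 and 892 at SNLD1, and 1 gene higher for injury in IP libraries. With it Sox11 over input at SNLD1 turned to 0.159, Sprr1a to 1.374 and the change for Atf3 to 0.118. The set tests of cell cycle genes by genotype in naive DRG (adjusted p = 0.887), of translation factors in the difference (0.979), and of ATF4 targets, sensory channels, translation factors and interferon-stimulated genes in the change of enrichment (0.992 each) turned direction without passing, and 1 list was called for that change. With the replicate block within IP and input 6 genes were higher with injury in IP libraries and 1 in inputs, and the change for Atf3 turned to 0.262.

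Leaving out 1 library turned these log2 values, given as ranges. In RNA-seq they were Jun by genotype at SNLD1 (−0.241 to 0.119), and Mettl14 (−0.115 to 0.103) and Gap43 (−0.0248 to 0.139) with injury in Mettl14cKO. For IP over input in naive DRG they were Mettl14 (−0.690 to 0.273), Sox11 (−2.85 to 0.697) and Sprr1a (−6.25 to 3.58), and at SNLD1 Sox11 (−0.640 to 0.239) and Sprr1a (−1.81 to 2.56). For the change they were Mettl14 (−0.955 to 0.153), Atf3 (−0.880 to 1.39), Sox11 (−0.852 to 2.69), Jun (−1.41 to 3.63), Gap43 (−0.760 to 0.621) and Sprr1a (−3.68 to 6.17). With injury in inputs they were Mettl14 (−0.444 to 0.319), Jun (−1.53 to 3.51), Gap43 (−0.248 to 0.452) and Sprr1a (−0.316 to 8.66), and in IP libraries Mettl14 (−1.06 to 0.0410) and Gap43 (−0.616 to 0.764). None of the reversed values passed a test. The Mettl14 level by genotype kept its direction and missed the threshold in the settings run for it, the tagged-gene tests by camera of the 5 RNA-seq comparisons missed it in all settings run for them, as did fry for movement one way, and the count of MeRIP-seq calls was 0 with any 1 library left out. Fry for change in either direction, which compares the set with no other genes, was under 0.05 for genotype at SNLD1, with an unadjusted mixed p of 0.0155 to 0.0392 over the site and background settings. With the replicate block it was 0.00317 there, 0.0113 for injury in wild type and 0.00434 in Mettl14cKO. The replicate block within IP and input could not be run for IP over input, which it would compare in replicate 1 only. Of the lists called with all libraries, 4 of 7, 5 of 6, 3 of 6 and 2 of 7 were called whichever 1 library was left out, for injury in wild type and Mettl14cKO and genotype in naive DRG and at SNLD1. Depth limits which transcripts can be measured: 3 counts amounted to between 1.95 and 3.54 CPM in the 3 shallowest MeRIP-seq libraries and 0.153 CPM in the deepest. Whether it limits the calls was not shown, since leaving out any 1 of those 3 libraries gave 0 calls.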

Other observations

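The tests of IP replicate 3, of the region around Mettl14, of m6A sites among shared genes and with the Y-linked covariate were chosen after the results were seen. The genes of the next paragraph were chosen after their values were seen.

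Ntf3, which encodes a survival factor for proprioceptive neurons, fell with injury in wild type from 4.70 ± 1.86 to 1.41 ± 0.729 CPM (log2 −1.73, edgeR adjusted p = 0.0390, n = 3) and stood at 12.3 ± 3.31 and 13.95 ± 0.550 CPM in naive and SNLD1 Mettl14cKO. That fall missed with only the 6 libraries compared (adjusted p = 0.1397), with the replicate block (0.0565) and without any 1 library other than naive library 1 (0.0626 to 0.155). The neuropeptide gene Gal stood at 136 ± 19.0 CPM in SNLD1 Mettl14cKO against 270.2 ± 90.8 CPM in wild type, and Npy at 1.85 ± 1.01 against 7.01 ± 3.21 CPM (adjusted p = 0.0850 and 0.123). Tph1 rose by a log2 of 2.41 in wild type, missing without naive library 3 (adjusted p = 0.0625), and 2.50 in Mettl14cKO. The mast cell protease Tpsab1, nearly absent from wild type, had no counterpart of that size in Cpa3 (log2 1.27, adjusted p = 0.0679), Tpsb2 (1.10, adjusted p = 0.123) or Cma1 (0.20, adjusted p = 0.876) between the genotypes at SNLD1, while Fcer1a was higher (2.29, adjusted p = 0.0282). Fcer1a missed with only the 6 libraries compared (adjusted p = 0.0556) and without any 1 library other than Mettl14cKO SNLD1 library 3 (0.0564 to 0.165).

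The SNL list held 1.29 times as many m6A sites as the naive list, and with 1 library per condition no difference in sites was tested. Among the genes with most sites, Dst (45 against 23), Ahnak2 (39 against 25) and Sptbn1 (45 against 29) exceeded that ratio, Ahnak (51 against 37) and Prune2 (56 against 43) lay near it, and Akap12 (38 against 43), Apc2 (35 against 40), Spock2 (36 against 40) and Map1a carried fewer. Immediate-early genes had 77 sites against 35. Sensory channels and receptors (173 against 132) followed the whole list at 1.31 times, and translation factors (130 against 91) had 1.43 times as many. Fibroblast markers had 6 against 19. The m6A machinery list was tagged itself, with 33 sites in naive and 38 in SNL ganglia.

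The 31 genes that differed by genotype in both conditions included more neighbours of Mettl14 than random gene sets, with 6 within 20 Mb (random median 0, permutation p = 1e-04, the smallest the draws can give). Sex is argued against, since 100% were still called in both conditions with the Y-linked share as a covariate. A candidate explanation for the chromosome 3 genes, among them Gbp2b, Ccdc109b and Tifa, is DNA of another strain carried along with the Mettl14 allele, although the labels give C57BL/6 for every library. Strain-derived DNA elsewhere stays open, since the 2 genes with a called neighbour within 2 Mb (random median 2, permutation p = 0.688) were Them5 and Pi4kb, on chromosome 3 themselves. Loss of m6A from the transcripts stays open, since 35.48% carried miCLIP sites, 11 genes against a median of 14 in matched random sets (permutation p = 0.883), and Gbp2b, Fn3krp and AI429214 were nearly absent from wild type, where miCLIP was made.

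IP replicate 3 of both conditions lay nearer to the inputs than the other IP libraries, with Spearman correlations of 0.873 and 0.897. Sequencing depth is argued against, since naive IP replicate 1, of like depth to SNLD1 IP replicate 3, had a correlation of 0.5246, and SNLD1 IP replicate 1, of like depth to naive IP replicate 3, 0.4915. Weak immunoprecipitation stays open: the excess of tagged genes was at most 0.3884 in these libraries and at least 0.849 in the others, as nearness to the inputs entails, and divided by the SD of the log2 ratio it was 0.4004 and 0.399 against 0.353 to 0.604. A separate library batch or counting run fits the values: 6 genes (0610010B08Rik, Gm10845, Gm15645, Gm19757, Tmsb15l and Vmn2r-ps129) had at least 50 counts in both and 0 in the other 8 MeRIP-seq libraries, where any other pair had 0. These genes were counted in every RNA-seq library, with lowest counts between 18 (0610010B08Rik) and 651 (Gm15645). Their counts of 0 are thus not explained by absence from the ganglia. A library batch and a counting run were not told apart. No biological explanation was tested.

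For groups of 3 against 3 the 10 splits are too few for a share under 0.05, and each count of splits as large includes the real one. The real split called 136 genes for injury in wild type (highest other 0, 1 split as large), 91 for injury in Mettl14cKO (highest other 161, 2 splits as large), 38 for genotype in naive DRG (highest other 0, 1 split) and 194 for genotype at SNLD1 (highest other 0, 1 split). The split with 161 sets Mettl14cKO naive library 1 and SNLD1 libraries 1 and 2 against the rest. It called more genes than injury did, which also points to a structure of these samples, and its cause was not tested. Its first 3 libraries had mean log2 levels of ribosomal protein genes of 7.72, 7.80 and 8.24. Mettl14cKO naive libraries 2 and 3 and SNLD1 library 3 stood at 7.34, 7.13 and 7.32. For injury in the IP libraries the real split called 0, so all 10 splits are as large by construction. Lists called numbered 7, 6, 6 and 7 in the real splits and up to 10, 7, 6 and 12 in others, with 6, 6, 2 and 5 splits as large. The tagged-gene p-values of 0.232, 0.326, 0.274 and 0.426 (camera) compared with 1.116e-09, 0.0824, 3.798e-09 and 1.245e-06 as the lowest of the others, with 8, 10, 9 and 10 splits as low. For injury in the IP libraries the highest other count was 221, which points to a structure of the samples. The split sets both replicate 2 libraries against both replicate 3 libraries, but another that does so called 0, so the replicate number alone does not account for it. With the replicate number as a block, 1 gene (common block) or 6 genes (block within IP and input) were called for injury there.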
